A study of Mus musculus with 14 samples.

How the data were processed

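Gene expression was measured in thymocytes of 14 mice, with 1 Affymetrix whole-transcript array per mouse. Per the labels, total RNA was isolated on silica columns and 100 ng was converted to sense cDNA, fragmented and labelled with biotin. The mice were wild type (WT) or homozygous for the p53 mutation R337H. They received 5 Gy of whole-body radiation 6 h before the thymocytes were taken, or no radiation.

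The deposited values are log2 expression per probe set from robust multi-array averaging (RMA), and the authors' notes name Partek 6.6. The log2 scale was read from the range of the values, 1.63 to 13.4, since the labels do not state it. Background correction, filters and summarization options were not stated. No value was missing and no gene had been centred. All 14 arrays and every column of values were used. For arrays, the number of mice limits the precision.

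Of 41345 probe sets, 23521 carried 1 gene symbol in the platform annotation, 1820 carried several and 16004 had no symbol. Genes were represented by the probe set with the highest mean over all arrays, which gave 22180 genes, 1082 of them with more than 1 probe set. Probe sets with no symbol or several were left out of the gene table and tested apart. Trp53 and Bax had no probe set of their own and were not analysed here, although both had been chosen as genes to name. Chromosomes and distances came from a reference gene table of assembly GRCm38.p6. The labels name no assembly, so no coordinate is given.

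A linear model with 4 group means was fitted to each gene over all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided). The WT irradiated group had 2 mice and shared the estimate of the spread with the other groups (10 residual and 5.68 prior degrees of freedom). The 5 contrasts were irradiation in WT, irradiation in the mutant, mutant against WT without irradiation, mutant against WT after irradiation, and the interaction. The interaction was the irradiation effect in the mutant minus that in WT. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Changes are given as log2 fold change ± standard error (SE).

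These tests, 29 gene lists and the settings below were chosen before the data were examined. The lists were 4 groups of p53 targets (arrest and feedback, death, DNA repair, metabolism and other) and their union of 73 measured genes. Further lists held the BCL2 family and caspases, G2/M genes, G1/S and replication genes, replication-dependent histones, DNA damage sensing and repair, interferon response, NF-kB targets, immediate early genes, glucocorticoid response and endoplasmic reticulum stress. Cholesterol synthesis, MYC and ribosome biogenesis, cytosolic ribosomal proteins and oxidative phosphorylation completed the pathway lists. Markers of 10 cell types were double negative, double positive and mature single positive thymocytes, natural killer and innate-like T cells, B cells, macrophages and dendritic cells, granulocytes, thymic epithelium, stroma and endothelium, and erythroid cells. Some genes sat in more than 1 list, such as Bbc3 and Apaf1 among p53 targets and the BCL2 family. Lists were tested with limma camera at a preset correlation of 0.01, adjusted over the lists of a contrast. An estimated correlation and fry were the alternatives.

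A p53 target score, the mean log2 value of the 73 targets, was compared between groups with two-sided exact permutation tests, 4 in the family. The sizes of both responses over these targets were compared by medians and by the slope through the origin, with 95% intervals from 1000 draws of mice within groups. Agreement across genes was measured by Pearson's r and Spearman's rho. Positions were tested with Fisher's exact test, two-sided.

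Named genes followed a fixed rule. It took up to 10 higher and 10 lower genes per contrast with the largest change among those passing whose groups did not overlap (without that condition for the interaction), skipping predicted genes, small RNAs and receptor segments. It also took up to 4 passing members of each list, or the 2 with the smallest p where none passed, and Cdkn1a, Mdm2, Bbc3 and Pmaip1 in every contrast. Genes outside it are marked as chosen after their values were seen.

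The alternatives were a filter on dim genes, quantile normalization again, centring of each array on its median, the mean of a gene's probe sets, arrays of the compared groups only, trend and robust variances, array weights, the replicate number as a replicate block, a change of at least 1 log2 unit, equal numbers of irradiated mice, and each array left out. Sex and a fat marker score as covariates, the inverse slope, lists of fat, airway and muscle genes, and the relations of the 10 marker lists to the fat genes (Pearson's r and Spearman's rho, permutation tests) were added after seeing the data. Sex was read from Xist.

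The pipeline was tested on simulated data with 22180 genes. Noise was drawn independently for each gene, with the same spread in all groups. The rates below hold for that setting and not for correlated genes or groups of unequal spread. Among genes given a change of 1 log2 unit, 87.5% were recovered for irradiation in WT, 96.2% for irradiation in the mutant, 97.5% for the genotypes without irradiation, 86.2% after irradiation and 82.5% for the interaction. Of genes called there, 2.8%, 4.7%, 7.3%, 2.1% and 2.4% were false, in the same order. Of genes given 0.5 log2 units, 35%, 60%, 57.5%, 38.8% and 20% were recovered, so many changes of that size would be missed, above all in the interaction. Preparation used Python 3.11.15 and NumPy 2.4.6, and figures were drawn with matplotlib 3.10.9.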

Results

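Thymocyte RNA from 14 mice was profiled on arrays, with 1 array per mouse. There were 4 non-irradiated WT mice, 2 irradiated WT mice, 4 non-irradiated mutant mice and 4 irradiated mutant mice. The mutant mice were homozygous for R337H, a missense change in the part of p53 that forms tetramers. The mutant allele was made in embryonic stem cells of a 129 strain and backcrossed to C57BL6/J. Median log2 values per array lay between 5.14 and 5.22, and correlations between arrays lay between 0.971 and 0.992. The 2 irradiated WT arrays stood apart, with interquartile ranges of 3.12 to 3.20 against 3.24 to 3.35 on all others, and irradiated WT mouse 1 had the lowest mean correlation (0.979). Every irradiation effect in WT, genotype difference after irradiation and interaction rests on these 2 arrays. The number of mice limits the precision, above all in the WT irradiated group.

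The comparison of irradiated with non-irradiated WT mice asked which transcripts respond to 5 Gy at 6 h in thymocytes with normal p53. Plk2, a polo-like kinase, rose by 4.22 ± 0.20 (log2 fold change ± SE, 18.7-fold, 2 irradiated against 4 non-irradiated mice, adjusted p = 1.37e-09). Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 3.13 ± 0.19 (8.75-fold). Bbc3, which encodes the pro-apoptotic protein Puma, rose by 3.00 ± 0.12 (7.98-fold). Tnfsf4, the ligand of the costimulatory receptor OX40, and Ccl3, a chemokine, rose by 3.38 ± 0.18 and 2.68 ± 0.32. Myc, a transcription factor of cell growth, fell by 1.71 ± 0.14 (3.28-fold lower, adjusted p = 1.2e-06).

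Among 73 measured p53 targets, 40 rose in irradiated WT mice and 33 did not pass, with 44 rising when adjusted over the list alone (camera adjusted p = 7.93e-45, and adjusted p = 1.95e-06 with an estimated correlation). In the arrest and feedback group 12 of 20 rose, also 12 when adjusted over the list alone, including Phlda3, an inhibitor of Akt signalling (3.45 ± 0.15), and Sesn2, a stress sensor upstream of mTOR (2.81 ± 0.16). Mdm2, the ubiquitin ligase that degrades p53, rose by 0.71 ± 0.09. Of 17 death genes, 12 rose (13 adjusted over the list alone), among them the nuclease gene Aen (2.41 ± 0.15), the apoptosome gene Apaf1 (2.39 ± 0.12) and Pmaip1, which encodes Noxa (0.97 ± 0.14). Of 9 repair genes, 3 rose (3 adjusted over the list alone), namely Polk (2.40 ± 0.10) and Mgmt (1.42 ± 0.18), a translesion polymerase and a methyltransferase, and the nuclease gene Ercc5 (1.32 ± 0.11). The repair list's camera adjusted p was 0.00382, and adjusted p = 0.139 with an estimated correlation. Its median was −0.05, its mean 0.51 and its tested direction up, and the median became 0.02 after quantile normalization. Of 30 metabolic and other targets, 16 rose (19 adjusted over the list alone), led by Dglucy, a D-glutamate cyclase (3.63 ± 0.09), and the death receptor gene Tnfrsf10b (2.38 ± 0.11).

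In the MYC and ribosome biogenesis list, 13 of 24 genes fell (18 adjusted over the list alone) and 1 rose (camera adjusted p = 2.82e-14, and adjusted p = 0.0303 with an estimated correlation). Examples were Gnl3, which encodes nucleostemin (−1.22 ± 0.12), the spermidine synthase gene Srm (−1.19 ± 0.14), and Polr1b, a subunit of RNA polymerase I (−1.02 ± 0.12). Cad, an enzyme of pyrimidine synthesis in that list, rose by 0.67. Of 41 G2/M genes, 4 fell (7 adjusted over the list alone), with Cdc25c at −0.64 ± 0.17, Cdc25b at −0.64 ± 0.14 and Ube2c at −0.54 ± 0.12 (camera adjusted p = 1.74e-05, and adjusted p = 0.578 with an estimated correlation). Of 41 G1/S and replication genes, 1 fell and 1 rose, the latter being E2f7, a repressor of E2F targets (0.76 ± 0.13). That list had a camera adjusted p of 0.0148 toward lower values, and adjusted p = 0.743 with an estimated correlation; adjusted over the list alone, 5 fell and 1 rose. Respiratory chain genes had 3 of 30 lower (5 adjusted over the list alone), led by Ndufa4 (−0.60 ± 0.12), with camera adjusted p = 2.56e-05 and adjusted p = 0.165 with an estimated correlation. Of 15 cholesterol synthesis genes, Sqle (−0.68 ± 0.17) and Sc5d (−0.55 ± 0.11) fell, 4 adjusted over the list alone (camera adjusted p = 0.000301, and adjusted p = 0.246 with an estimated correlation).

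Stress and signalling genes moved both ways. Of 20 immediate early genes, 8 rose and 2 fell (8 and 4 adjusted over the list alone), with the transcription factor genes Jun at 1.76 ± 0.33 and Atf3 at 1.44 ± 0.19 (camera adjusted p = 0.0138, and adjusted p = 0.505 with an estimated correlation). Of 16 glucocorticoid response genes, 4 rose, namely Ddit4 (1.31 ± 0.23), Dusp1 (0.84 ± 0.14), Txnip (0.64 ± 0.11) and Pik3ip1 (0.60 ± 0.11). Adjusted over the list alone, 5 of them rose and 1 fell; the camera adjusted p was 0.000875, and adjusted p = 0.262 with an estimated correlation. In the BCL2 family and caspases, 4 of 25 rose (Bbc3, Apaf1, Pmaip1 and Bcl2l11) and 2 fell, 4 and 4 when adjusted over the list alone. Camera did not call the list (adjusted p = 0.287), while fry called it upward (adjusted p = 0.000379). Its median was −0.04 and its mean 0.20. Of 19 NF-kB targets, 3 rose and 2 fell (4 and 3 adjusted over the list alone), with Il1b at 1.41 ± 0.19 and Lta at −0.75 ± 0.14 (camera adjusted p = 0.937). Of 19 replication-dependent histone genes, H4c8 (1.32 ± 0.20) and H4c1 (1.26 ± 0.21) rose and H2bc12 fell (−0.64 ± 0.14), the same counts of 2 and 1 as when adjusted over the list alone (camera adjusted p = 0.412). Of 34 DNA damage sensing and repair genes, 2 fell (2 adjusted over the list alone), Ung (−0.53 ± 0.11) and Parp2 (−0.41 ± 0.11), with camera adjusted p = 0.416. Mx1 rose among 24 interferon response genes (0.80 ± 0.19, 1 adjusted over the list alone, camera adjusted p = 0.783). Sdf2l1 fell among 17 endoplasmic reticulum stress genes (−0.49 ± 0.12, 1 adjusted over the list alone, camera adjusted p = 0.19). Cytosolic ribosomal proteins had 0 of 39 genes passing in limma, 8 at an unadjusted p under 0.05, and 1 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0628).

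Camera at the preset correlation called 3 lists of cell type markers toward lower values in irradiated WT mice. Among mature single positive thymocyte markers, 5 of 22 fell and 1 rose (9 and 1 adjusted over the list alone), with the chemokine receptor gene Ccr4 at −0.68 ± 0.14, Cd52 at −0.51 ± 0.09 and Slfn2 at 0.52 ± 0.10 (camera adjusted p = 2.51e-05, and adjusted p = 0.165 with an estimated correlation). Of 14 double negative thymocyte markers, 4 fell (5 adjusted over the list alone, with 1 rising). They were Ptcra, the pre-T cell receptor alpha chain (−0.86 ± 0.17), Il2ra (−0.76 ± 0.17), Dtx1 (−0.69 ± 0.13) and Gata3 (−0.56 ± 0.12), with camera adjusted p = 0.0406 and adjusted p = 0.211 with an estimated correlation. Of 13 B cell markers, 3 fell and 1 rose (6 and 1 adjusted over the list alone), with Bank1 at −0.80 ± 0.15 and the transcription factor gene Spib at 1.35 ± 0.19 (camera adjusted p = 0.00275, and adjusted p = 0.365 with an estimated correlation). Among 15 natural killer and innate-like T cell markers, the cytotoxic protease gene Gzma (−1.62 ± 0.18) and the chemokine gene Xcl1 (−0.77 ± 0.17) fell (2 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.802). Camera did not call double positive thymocytes (adjusted p = 0.394), macrophages and dendritic cells (0.157), granulocytes (0.223), thymic epithelium (0.0931), stroma and endothelium (0.969) or erythroid cells (0.769). Some lists were called in irradiated WT mice only at the preset correlation. Of these, fry called repair targets (adjusted p = 3.12e-06), respiratory chain genes (0.00454), cholesterol synthesis (0.0169) and glucocorticoid response (0.0444). It also called mature single positive (0.00698) and double negative thymocytes (0.00789). G2/M (0.235), G1/S (0.514), immediate early genes (0.126) and B cells (0.0858) were not called by fry.

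In total, 1073 of 22180 genes passed in irradiated WT mice, 416 higher and 657 lower, and 140 of them changed by at least 1 log2 unit (114 higher and 26 lower). After quantile normalization the split was 491 higher and 470 lower, or 51.1% higher against 38.8%, and among genes above the median level it was 471 and 1023 (31.5%). Without irradiated WT mouse 1 it was 236 and 211 (52.8%). The group had 2 mice: without irradiated WT mouse 1 the count was 447, and without irradiated WT mouse 2 it was 623.

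The same comparison in mutant mice asked what remained of the response when p53 carried the mutation. Dglucy rose by 2.86 ± 0.08 (7.28-fold, 4 irradiated against 4 non-irradiated mice, adjusted p = 2.02e-12), Plk2 by 2.48 ± 0.16 (5.59-fold) and Cdkn1a by 2.30 ± 0.16 (4.92-fold). Bbc3 rose by 1.68 ± 0.10 (3.21-fold) and Pmaip1 by 0.86 ± 0.12 (1.81-fold). The change of Mdm2 was 0.15 ± 0.08 and did not pass (adjusted p = 0.447). Gzma (−1.10 ± 0.14), Srm (−1.06 ± 0.12) and Myc (−0.83 ± 0.12) fell.

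Of the 73 p53 targets, 28 rose in irradiated mutant mice and 45 did not pass, with 37 rising when adjusted over the list alone (camera adjusted p = 1.47e-35, and adjusted p = 3.59e-06 with an estimated correlation). The risers included 10 of 20 arrest and feedback genes (10 adjusted over the list alone), such as Phlda3 (2.32 ± 0.12) and Sesn2 (2.84-fold), and 9 of 17 death genes (13), such as Tnfrsf10b (2.04 ± 0.09), Aen (1.28 ± 0.12) and Apaf1 (1.17 ± 0.10). Among repair genes 2 of 9 rose (3 adjusted over the list alone), Polk (1.58 ± 0.08) and Ercc5 (0.53 ± 0.09), with camera adjusted p = 0.00201 and adjusted p = 0.099 with an estimated correlation. Of 30 metabolic and other targets 10 rose (15 adjusted over the list alone), including Cd80, a costimulatory ligand (1.22 ± 0.18), and Ddit4 (0.83 ± 0.19). In the BCL2 family and caspases 3 rose and 2 fell (3 and 2 adjusted over the list alone), the latter including Bid (−0.49 ± 0.09). Camera did not call that list (adjusted p = 0.288), while fry called it upward (adjusted p = 0.00515). The list had a median of 0 and a mean of 0.12.

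Ribosome biogenesis genes fell in the mutant as well, with 10 of 24 lower (18 adjusted over the list alone, camera adjusted p = 4.26e-22, and adjusted p = 0.00682 with an estimated correlation). Gnl3 fell by 0.87 ± 0.10 and Polr1b by 0.67 ± 0.10. Of 41 G1/S and replication genes, Uhrf1 (−0.60 ± 0.13) and Mcm3 (−0.50 ± 0.11) fell and E2f7 rose (0.53 ± 0.11), with 12 lower and 1 higher when adjusted over the list alone (camera adjusted p = 1.46e-09, and adjusted p = 0.355 with an estimated correlation). The mitotic gene Cenpa (−0.45 ± 0.10) was the single G2/M gene that passed over all genes, against 20 lower when adjusted over the list alone (camera adjusted p = 1.97e-15, and adjusted p = 0.242 with an estimated correlation). The checkpoint kinase gene Chek1 (−0.70 ± 0.14) and Ung (−0.55 ± 0.09) fell in the DNA damage list (2 adjusted over the list alone), which camera did not call (adjusted p = 0.852). Camera called markers of stroma and endothelium upward relative to other genes (median 0.26, adjusted p = 0.000916, and adjusted p = 0.355 with an estimated correlation), although 0 of 16 passed in limma and 4 had an unadjusted p under 0.05. Over the 14 arrays their mean followed that of 12 fat genes, a list written after the data were seen, with Pearson's r of 0.88 (permutation p = 7e-05), Spearman's rho of 0.873 (permutation p = 0.00013) and r of 0.811 without the 2 farthest arrays. Adjusted over the relations of 10 marker lists, also chosen after the data were seen, the permutation p were 7e-04 and 0.0013. Interferon response genes (median 0.21) were called upward by camera, with adjusted p = 9.18e-05 and adjusted p = 0.252 with an estimated correlation. Of these 24 genes, 0 passed in limma, 6 had an unadjusted p under 0.05, and 2 rose when adjusted over the list alone. Camera also called histones, endoplasmic reticulum stress, cholesterol synthesis, ribosomal proteins and oxidative phosphorylation downward and glucocorticoid response and double positive thymocytes upward. Their adjusted p lay between 0.0655 and 0.393 with an estimated correlation. Fry called ribosomal proteins (adjusted p = 0.00479), oxidative phosphorylation (0.0125), endoplasmic reticulum stress (0.0288), histones (0.0415) and double positive thymocytes (0.00355), in the same directions. Cholesterol synthesis (0.0937) and glucocorticoid response (0.188) were not called by fry. The mean of the double positive markers and that of the 12 fat genes had r of −0.213 over the 14 arrays (permutation p = 0.46). With each group's mean subtracted, r was −0.892. The ribosomal protein gene Rpl3 fell by 0.58 ± 0.13.

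Altogether 282 genes passed in the mutant, 137 higher and 145 lower (48.6% higher), with 35 changing by at least 1 log2 unit (32 higher and 3 lower). The balance depended on the setting: fitting the mutant arrays alone gave 111 higher and 66 lower (62.7%), leaving out irradiated mutant mouse 4 gave 102 and 50 (67.1%), and genes above the median level gave 195 and 288 (40.4%). Leaving out 1 mouse gave 180 without non-irradiated mutant mouse 1 and 146 without non-irradiated mutant mouse 4, and 170, 178 and 152 without irradiated mutant mice 2, 3 and 4. With 2 of the 4 irradiated mutant mice, to match WT, the median count over 6 pairs was 121.5 (range 77 to 263).

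Both genotypes moved many of the same genes. Of the 416 genes raised in WT, 112 also passed as higher in the mutant, against 2.57 expected from independent calls. Of the 657 lowered in WT, 104 also passed as lower, against 4.3 expected. No gene passed in opposite directions (0 of 1073 in limma). Across all 22180 genes, which are not independent replicates, the log2 fold changes of both genotypes had Pearson's r of 0.436 and Spearman's rho of 0.253. Among the 11090 genes above the median level r was 0.567, and without the p53 targets it was 0.385.

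The interaction asked whether the response itself differed between genotypes. Plk2 responded less in the mutant, by −1.74 ± 0.26 (adjusted p = 0.0107), Bbc3 by −1.31 ± 0.16 (0.0029), Sesn2 by −1.30 ± 0.21 (0.0175) and Apaf1 by −1.22 ± 0.15 (0.0029). Prrg4, a membrane protein gene, and Aldh4a1, an enzyme of proline breakdown, also responded less (−1.23 ± 0.16 and −1.14 ± 0.15). The 8 genes with a higher interaction included Il17rb, a cytokine receptor gene (0.96 ± 0.17), Ndufaf6, an assembly factor of respiratory complex I (0.88 ± 0.16), and Atat1, a tubulin acetyltransferase gene (0.87 ± 0.14).

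In all, 46 genes passed the interaction, 38 lower and 8 higher (17.4% higher). The share was 30.9% among genes above the median level (29 higher and 65 lower) and 27.6% with trend and robust variances (24 and 63). It was 10.3% after quantile normalization (7 and 61) and with arrays centred on their medians (4 and 35), 5% without non-irradiated mutant mouse 4 (1 and 19), and 0% without irradiated WT mouse 1 (0 higher and 14 lower in limma). The p53 targets held 14 of the 46, which rose to 26 when adjusted over the list alone (camera adjusted p = 2.02e-20, and adjusted p = 3.99e-05 with an estimated correlation). They were 7 of 20 arrest and feedback genes (10 adjusted over the list alone), including Gtse1 (−1.14 ± 0.14) and Phlda3 (−1.13 ± 0.19), 5 of 17 death genes (8), including Aen (−1.14 ± 0.20), 2 of 9 repair genes (3), Polk (−0.82 ± 0.12) and Ercc5 (−0.79 ± 0.14), and 1 of 30 metabolic and other genes (3), Dglucy (−0.77 ± 0.12). The repair list had a camera adjusted p of 0.032, and adjusted p = 0.279 with an estimated correlation; its median was 0.02, its mean −0.23 and its tested direction down. The metabolic list had a camera adjusted p of 5.51e-06, and adjusted p = 0.0576 with an estimated correlation. For Cdkn1a the interaction was −0.83 (95% interval −1.36 to −0.30, adjusted p = 0.252) and for Mdm2 −0.56 (−0.82 to −0.30, adjusted p = 0.0816), so neither passed. Cdkn1a stood at 6.707 in non-irradiated mutant mouse 2, against 7.496 to 7.53 in the rest of its group. That low value adds to its rise in the mutant. Pmaip1 had an interaction of −0.12 (−0.51 to 0.28, adjusted p = 0.896), an interval that leaves room for a smaller or a larger response.

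Median changes of the 73 targets were 0.53 in WT (95% interval 0.49 to 0.63) and 0.33 in the mutant (0.22 to 0.36). Their median difference was −0.24 (95% interval −0.36 to −0.19), and the slope of the mutant on the WT changes was 0.616 (95% interval 0.582 to 0.642). Noise in the WT changes pulls this slope down, and the inverse of the slope of WT on mutant changes, added after the data were seen, was 0.659 (95% interval 0.629 to 0.726). The draws took the irradiated WT group from 2 mice, so all of these intervals are likely too narrow. Of the 40 targets raised in WT, 39 changed less in the mutant, a share no higher than over all genes, where 411 of 416 raised in WT (98.8%) and 641 of 657 lowered (97.6%) changed less. The median ratio of log2 fold changes of the 40 was 0.552. The median ratio was 0.552 for 12 arrest and feedback genes, 0.573 for 12 death genes, 0.403 for 3 repair genes and 0.603 for 16 metabolic and other genes. The lowest ratios belonged to Ptpn14, a phosphatase gene (0.173), and Mdm2 (0.207), and the highest to Cd80 (1.02). These 40 genes were selected for their WT change, which by itself favours smaller changes in the mutant.

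**Figure D1:**
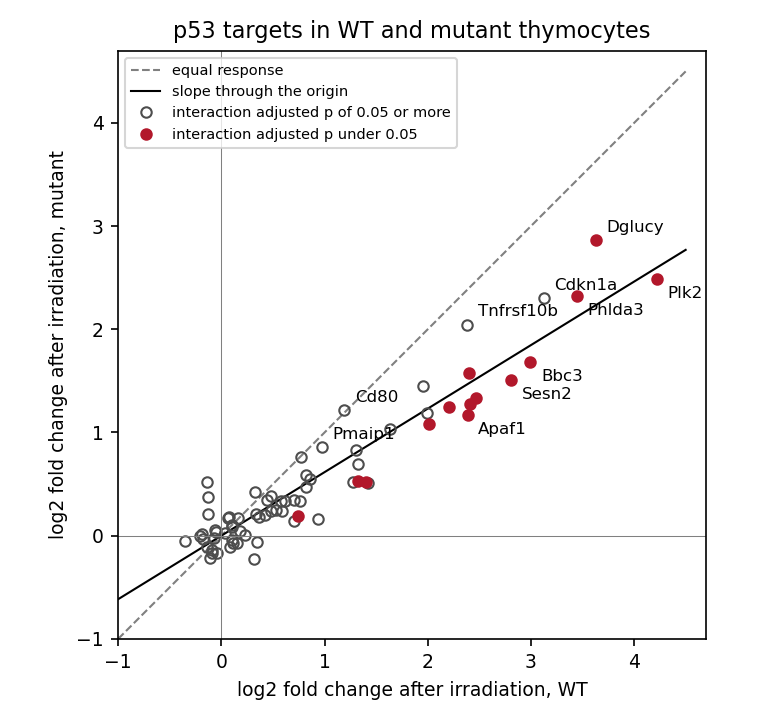
Log2 fold change after irradiation in mutant mice (vertical axis) against that in WT mice (horizontal axis) for the 73 p53 targets, 1 point per gene. Filled points passed the interaction test, the dashed line marks equal responses, and the solid line is the slope through the origin of 0.616 (the inverse slope was 0.659); Plk2 lies at 4.22 and 2.48.

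Camera at the preset correlation also called marker lists in the interaction. Mature single positive thymocyte markers had a median of 0.27 (camera adjusted p = 2.16e-05, and adjusted p = 0.228 with an estimated correlation), thymic epithelium 0.43 (0.00371, and adjusted p = 0.537 with an estimated correlation) and B cells 0.27 (0.0149, and adjusted p = 0.537 with an estimated correlation). Double negative thymocyte markers had 0.13 (0.032, and adjusted p = 0.228 with an estimated correlation), stroma and endothelium 0.22 (0.032, and adjusted p = 0.59 with an estimated correlation) and granulocytes −0.15 (0.0495, and adjusted p = 0.59 with an estimated correlation). Of their members 0 passed the interaction in limma, while 8, 4, 4, 6, 1 and 1 had an unadjusted p under 0.05, in that order. Thymic epithelium markers followed the same 12 fat genes over the 14 arrays with r of 0.746 (permutation p = 0.0017, 0.0085 adjusted over the 10 lists), rho of 0.793 (permutation p = 0.001, adjusted 0.005) and r of 0.627 without the 2 farthest arrays. The interferon list had a median of 0.20 (0.004, and adjusted p = 0.537 with an estimated correlation). Junb (−0.81 ± 0.16) was the single immediate early gene that passed, in a list with a camera adjusted p of 0.0495 and adjusted p = 0.566 with an estimated correlation. The glucocorticoid list gave the same pair of values. The interaction count was 14 and 28 without irradiated WT mice 1 and 2, 20 without non-irradiated WT mouse 4, 20 without non-irradiated mutant mouse 4, and 23 without irradiated mutant mouse 2 or 3. With trend and robust variances it was 87.

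The comparison of genotypes without irradiation asked whether the mutation alters resting thymocytes. Dgke, a diacylglycerol kinase gene, was lower in the mutant by −2.22 ± 0.18 (4.65-fold, 4 against 4 mice, adjusted p = 1.43e-05), and Ybx2, a germ cell RNA-binding protein gene, by −1.33 ± 0.12 (adjusted p = 9.1e-05). Malt1, a protease of lymphocyte receptor signalling, was lower by −0.71 ± 0.10 (adjusted p = 0.00797). Lrp12, a receptor gene (0.72 ± 0.11), Dpf1, a chromatin factor gene (0.63 ± 0.10), and Tiparp, an ADP-ribosyltransferase gene (0.59 ± 0.09), were higher. Gm525, a predicted gene named after its values were seen because the count was small, was lower by −2.14 ± 0.14.

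These 7 genes were all that passed, 3 higher and 4 lower, against 1418 at an unadjusted p under 0.05. The split was 2 higher and 5 lower after quantile normalization (28.6% higher against 42.9%), 5 and 4 with arrays centred on their medians, among genes above the median level or without non-irradiated mutant mouse 2 (55.6% each), and 6 and 5 with trend and robust variances (54.5%). It was 1 and 4 on the 8 non-irradiated arrays alone and without non-irradiated WT mouse 2 or 3 (20% each), and 2 and 5 without non-irradiated WT mouse 4. Without non-irradiated WT mouse 1, mutant mouse 1 or mutant mouse 4, 0 genes were higher in limma and 3, 5 and 4 lower. Lrp12, Dpf1 and Tiparp thus all failed to pass without any 1 of these 3 mice, as they did without non-irradiated WT mouse 3 and on the 8 arrays alone, and Malt1 did not pass without non-irradiated WT mouse 1. Of the p53 targets, 0 of 73 passed in limma, 10 had an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone; neither camera (adjusted p = 0.875) nor fry (adjusted p = 0.934) called the list. Its median was 0.01, its mean −0.02 and its tested direction up. Within it camera called arrest and feedback genes upward (0.0315, and adjusted p = 0.354 with an estimated correlation) and metabolic and other targets downward (0.0203, and adjusted p = 0.509 with an estimated correlation), and fry called neither. The p53 target score was 6.93 ± 0.04 (SD, n = 4) in WT and 6.91 ± 0.03 (SD, n = 4) in mutant mice, a difference of −0.02 (exact permutation p = 0.571).

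Camera called 16 lists without irradiation at the preset correlation, these 2 groups of p53 targets among them. Fry called 0 lists in its directional test. Its mixed test, which counts changes in either direction, called lists that included mature single positive thymocytes (adjusted p = 0.00174). Death targets of p53 (0.00861) and the BCL2 family and caspases (0.009) were also called by the mixed test. With an estimated correlation camera called 0 lists, the adjusted p of the 16 lying between 0.354 and 0.544. The other 8 downward calls were mature single positive thymocytes (median −0.20, adjusted p = 1.03e-07), macrophages and dendritic cells (−0.23, the same p), B cells (−0.22, 2.96e-05), stroma and endothelium (−0.16, 0.000306), thymic epithelium (−0.20, 0.00137), natural killer and innate-like T cells (−0.09, 0.0194), NF-kB targets (−0.08, 0.0315) and interferon response (−0.13, 0.038), with adjusted p = 0.354 or more with an estimated correlation. The other 6 upward calls were G2/M genes (37 of 41 with a positive change, adjusted p = 4.42e-05), G1/S and replication genes (36 of 41, 6.12e-05), granulocytes (14 of 14, 0.00759), MYC and ribosome biogenesis (20 of 24, 0.00847), cholesterol synthesis (12 of 15, 0.0315) and DNA damage sensing and repair (23 of 34, 0.0414), each with adjusted p = 0.544 with an estimated correlation. Of the members of these 14 lists 0 passed in limma, and in the order given 9, 7, 4, 4, 2, 2, 3, 2, 3, 1, 1, 1, 0 and 1 had an unadjusted p under 0.05; adjusted over the list alone, 8 of 22 mature single positive, 3 of 13 B cell, 1 of 16 stroma and 1 of 15 natural killer markers were lower and 1 of 24 interferon genes higher. The non-irradiated mutant mice were also the baseline of the irradiation effect in the mutant and of the interaction, so these differences enter the cell cycle and marker values there with the opposite sign. The mean of the 21 macrophage and dendritic cell markers and that of the 12 fat genes had Pearson's r of 0.594 over the 14 arrays (permutation p = 0.027, 0.09 adjusted over the 10 lists), rho of 0.635 (permutation p = 0.017, adjusted 0.057) and r of 0.493 without the 2 farthest arrays. Il7r, the interleukin 7 receptor gene, stood at −0.53 ± 0.09 (adjusted p = 0.0533).

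Dgke, Ybx2 and Gm525 all lay on chromosome 11 within 20 Mb of Trp53 in assembly GRCm38.p6. Those 3 of 7 genes (42.9%) compared with 3.32% of all genes tested in that window (Fisher's exact p = 0.00116) and with 7.5% on the chromosome (Fisher's exact p = 0.0117). Within 10 Mb the share was 14.3% (Fisher's exact p = 0.122). After irradiation all 3 were again lower in the mutant, Dgke by −1.49 ± 0.21, Ybx2 by −1.24 ± 0.15 and Gm525 by −1.67 ± 0.18. Of the 253 genes that differed between irradiated genotypes, 14 (5.5%) lay within 20 Mb of Trp53 (Fisher's exact p = 0.0735). Among the 35 that differed by at least 1 log2 unit there were 5 (14.3%, Fisher's exact p = 0.00568), these 3 included.

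The last comparison set irradiated mutant mice against irradiated WT mice. Plk2 was lower in the mutant by −1.54 ± 0.20 (2.91-fold, 4 against 2 mice, adjusted p = 0.00127), Phlda3 by −1.28 ± 0.15, Apaf1 by −1.06 ± 0.12 and Bbc3 by −1.06 ± 0.12. Cox6b2, a subunit of cytochrome oxidase (−1.41 ± 0.19), and Thbs1, which encodes thrombospondin (−1.33 ± 0.26), were lower too. Myc was higher by 0.99 ± 0.14 (adjusted p = 0.00241), and so was Angpt1, a vascular growth factor gene (1.29 ± 0.18). Among the named genes the largest difference upward was that of Zfp39, a zinc finger gene (2.45 ± 0.55, adjusted p = 0.0396), followed by Hif3a (1.52 ± 0.34, adjusted p = 0.0402).

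Of 73 p53 targets, 22 were lower in the irradiated mutant (31 adjusted over the list alone, camera adjusted p = 1.07e-23, and adjusted p = 3.91e-05 with an estimated correlation). They included 9 of 20 arrest and feedback genes (11 adjusted over the list alone), among them Cdkn1a (−0.88 ± 0.19, adjusted p = 0.0372), and 8 of 17 death genes (10). All 3 repair genes raised in WT were lower, Mgmt (−0.92 ± 0.18), Polk (−0.81 ± 0.10) and Ercc5 (−0.73 ± 0.11), 3 also when adjusted over the list alone, although camera did not call the list (adjusted p = 0.158). Ptpn14 (−1.14 ± 0.14) and Notch1, a receptor of early T cell development (−0.72 ± 0.12), were 2 of the 4 lower genes among 30 metabolic and other targets (11 adjusted over the list alone). Mdm2 (−0.36 ± 0.09, adjusted p = 0.08) and Pmaip1 (0.09 ± 0.14, adjusted p = 0.822) did not pass. The p53 target score was 7.81 ± 0.05 (SD, n = 2) in irradiated WT and 7.45 ± 0.04 (SD, n = 4) in irradiated mutant mice. That difference of −0.36 had an exact permutation p of 0.0667, the smallest that 4 against 2 mice allow, and was larger than the spread within either group. Irradiated and non-irradiated mice differed in score by 0.89 in WT (exact permutation p = 0.0667, the smallest possible) and by 0.54 in the mutant (exact permutation p = 0.0286, the smallest possible). Adjusted over the 4 exact permutation tests, these 3 had p = 0.0889. With so few mice no adjusted value of this family could have fallen under 0.05, so that outcome was fixed beforehand.

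**Figure D2:**
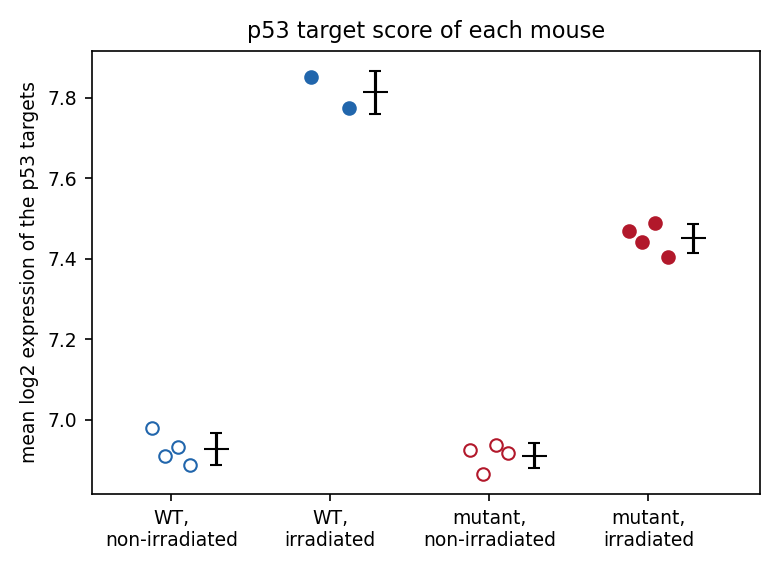
Mean log2 expression of the 73 p53 targets (vertical axis) in each mouse of the 4 groups, with 1 point per mouse and the group mean ± SD in black. The irradiated WT mean was 7.81 and the irradiated mutant mean 7.45, with non-irradiated means of 6.93 and 6.91; the vertical axis does not start at 0.

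Camera called the MYC and ribosome biogenesis list upward relative to other genes (adjusted p = 0.00194, and adjusted p = 0.449 with an estimated correlation). Over all genes Cad alone of its 24 members passed, lower by −0.48 ± 0.10, while 12 were higher and 3 lower adjusted over the list alone. Cholesterol synthesis was also called upward (0.00292, and adjusted p = 0.449 with an estimated correlation), with 0 of 15 genes passing in limma, 5 at an unadjusted p under 0.05 and 3 higher adjusted over the list alone. Downward calls by camera were those of glucocorticoid response (0.00057, and adjusted p = 0.381 with an estimated correlation), cytosolic ribosomal proteins (0.00292, and adjusted p = 0.449 with an estimated correlation) and macrophages and dendritic cells (0.0263, and adjusted p = 0.683 with an estimated correlation). In these 3 lists 0 of 16, 0 of 39 and 0 of 21 genes passed in limma, also 0 adjusted over the list alone, and 6, 3 and 3 had an unadjusted p under 0.05. Xaf1, an interferon-induced gene, was higher by 0.70 ± 0.14. Among NF-kB targets Il1b (−0.98 ± 0.19) was lower and Lta (0.67 ± 0.14) and Nfkbie (0.46 ± 0.10) were higher.

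Altogether 253 genes differed after irradiation, 109 higher and 144 lower, 35 of them by at least 1 log2 unit (6 higher and 29 lower). The balance depended on the setting: 75 were higher and 184 lower after quantile normalization (29% higher against 43.1%), 305 and 183 among genes above the median level (62.5%), 232 and 203 with the fat score as covariate (53.3%), and 188 and 175 with trend and robust variances (51.8%). The count was 40 without irradiated WT mouse 1 (6 higher and 34 lower, 15%), 156 without irradiated mutant mouse 2 and 160 without irradiated mutant mouse 4, and 259 without irradiated WT mouse 2. The 2 irradiated WT mice differed in transcripts of other tissues: the mean of 11 airway genes was 5.83 and 4.3, and that of 12 fat genes 6.32 and 5.44, both lists having been written after the data were seen.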

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

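The tests of compressed signal and of linked 129 sequence were chosen only after the result they measure was seen, and the fat, airway and muscle lists were written after the first such genes were noticed. The explanations below were tested on the data in which the patterns were found.

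The response of the p53 targets was smaller in the mutant, with a median difference of −0.239 over 73 genes, and 18 named genes passed the test of the difference itself. Lower responses were those of Plk2 (−1.74), Bbc3 (−1.314), Sesn2 (−1.304), Prrg4 (−1.234), Apaf1 (−1.223), Gtse1 (−1.139), Aldh4a1 (−1.137), Aen (−1.136), Phlda3 (−1.128), Inka2 (−1.121), Polk (−0.823), Junb (−0.813), Ercc5 (−0.791) and Dglucy (−0.767). Il17rb (0.96), Ndufaf6 (0.884), Atat1 (0.873) and Srsf10 (0.727) had higher values.

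The tables argue against 1 array setting the WT response, since the median difference stayed at −0.213 or lower without either irradiated WT array. The spread over resampled mice was 0.045, which is likely too small with 2 irradiated WT mice. Compressed signal on the mutant irradiated arrays would need narrower values there, but their lowest interquartile range exceeded the highest of the WT irradiated arrays by 0.071. It was the 2 WT irradiated arrays that stood apart, at 3.121 to 3.197 against 3.243 to 3.347 on all others, and with all arrays given the same distribution by quantile normalization the median difference was −0.235. A different mix of cell types, fewer responding cells among them, cannot be told apart from lower p53 activity in each cell. The largest median interaction of a marker list, 0.425 for thymic epithelium, was upward, but it was larger in size than that of the p53 targets. As a mean over its markers it was 0.375 ± 0.271 (SE). By that measure mature single positive thymocytes had 0.237 ± 0.076 and double negative thymocytes 0.233 ± 0.07. Only granulocytes (−0.157 ± 0.205) and erythroid cells (−0.157 ± 0.099) had downward means. Lower activity of the mutant p53 may underlie the pattern, as the design allows, and stays a hypothesis.

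Of the 7 genes that differed between genotypes without irradiation, 3 lay within 20 Mb of Trp53. A candidate explanation is 129 sequence linked to the targeted allele, which predicts such a cluster (Fisher's exact p = 0.00116); within 10 Mb the share was 14.3% (Fisher's exact p = 0.122). Reduced p53 activity in resting cells would need these genes to rise after irradiation in WT mice, where their median change was −0.493. That value lies outside the band of −0.25 to 0.25 written beforehand, on the side away from the prediction, and none of the 3 passed in limma (the smallest adjusted p was 0.138). A sequence difference under a probe and a difference in expression remain open, as no sequence was available.

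Fat and airway genes differed between mice of the same group. Fat tissue carried into some preparations is a candidate explanation: 12 fat genes not used to notice the pattern followed 6 others with Pearson's r of 0.961 over 14 arrays (permutation p = 1e-05, the smallest the permutations give) and Spearman's rho of 0.987 (permutation p = 1e-05), and r was 0.969 without the 2 farthest arrays. Airway genes followed the same 6 with r of 0.542 (permutation p = 0.034), rho of 0.705 (permutation p = 0.0056) and r of 0.579 without the 2 farthest arrays, and muscle genes with r of 0.537 (permutation p = 0.047), rho of 0.455 (permutation p = 0.1) and r of 0.459. Over these 3 relations the adjusted permutation p were 3e-05, 0.047 and 0.047, and the airway score stood out in non-irradiated WT mouse 2 (6.35) and irradiated WT mouse 1 (5.83), with 4.74 the highest elsewhere. Over the arrays Fabp4 ranged from 7.1 to 9.76 and the brown fat gene Ucp1 from 5.24 to 7.84. The fat genes Adipoq and Plin1 varied less, from 4.93 to 5.81 and from 5.34 to 6.47. No sort is described that would remove such tissue.

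In fits of the 8 mutant arrays alone, splitting them into 4 and 4 gave as many genes as the real split in 1 of 35 splits, the real split itself. It gave 177 genes against 0 at most in the others. These counts argue against chance for irradiation in the mutant, although 1 of 35 is the smallest share the test can give. For the 8 non-irradiated arrays the share was also 1 of 35, with 5 genes against 4 at most in the others. With so few genes and the smallest share possible, chance cannot be firmly excluded for that count. Nor can it be excluded gene by gene for the 7 reported, of which that fit called 4. Over all 14 arrays the count of 7 became 3 without non-irradiated WT mouse 1 and 4 without non-irradiated mutant mouse 4. The highest other split put all females against all males, so its 4 genes do not measure chance alone. The only further split with any gene had 1.

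A single array lay far from the other 3 of its group in 13 of 399 tests, where about 20 are expected by chance. The share of the range taken by that gap was 0.871 for Ier3, 0.91 for Dgke and 0.882 for the double negative thymocyte score in non-irradiated WT mice. In non-irradiated mutant mice it was 0.958 for Cdkn1a, 0.867 for Il2ra, 0.849 for H4c8, 0.873 for the endoplasmic reticulum stress score, 0.882 for the cholesterol score and 0.943 for the erythroid score. In irradiated mutant mice it was 0.864 for Tmem97, 0.974 for Bcl2l11, 0.924 for Gata3 and 0.871 for the BCL2 family score.

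Signals also appeared among the 17824 probe sets with no symbol or several, which the gene comparisons leave out. There 373 passed for irradiation in WT, 10 for irradiation in the mutant and 323 for mutant against WT after irradiation. In limma 0 passed for the genotypes without irradiation (781 at an unadjusted p under 0.05) and 0 for the interaction (1919 at an unadjusted p under 0.05).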

How the results depend on the processing

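Sex and fat score as covariates and the inverse slope were chosen after seeing the data. No named gene reversed its direction in a contrast where it had passed: 3123 such values still passed and 511 no longer passed. Named genes were not followed in contrasts where they had not passed. For lists (estimated correlation, fry, genes above the median level) 298 kept direction and side, 109 no longer passed, 6 newly passed and 17 reversed, none of these 17 called before or after. Where 1 irradiated WT mouse was left, it was assumed to vary like the other groups. The interaction on arrays of the compared groups only is the fit reported and was not run again. The cause was not tested for any change below except where fewer genes or fewer arrays entered.

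With only genes above the median level, so fewer tests, 483 genes passed for irradiation in the mutant, 488 for the genotypes after irradiation and 94 for the interaction; the WT median change was 0.589, r across genes 0.567, and 10 lists were called without irradiation. Trend and robust variances gave 11 genes without irradiation and 87 for the interaction. Array weights gave 163 genes after irradiation. With only the arrays compared, so fewer arrays, 617 genes passed for irradiation in WT, 177 in the mutant and 107 after irradiation. A change of at least 1 log2 unit left 140, 35, 3, 35 and 17 genes for irradiation in WT, in the mutant, genotypes without and after irradiation, and the interaction. Using 2 of the 4 irradiated mutant mice gave medians of 121.5 and 20.5 genes for irradiation in the mutant and the interaction. The fat score as covariate gave 435 genes after irradiation, and sex gave 1095, 250, 8, 197 and 42 genes in the order above.

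Centring arrays on their medians reversed the score difference without irradiation to 0.03. Quantile normalization moved the WT median change from 0.525 to 0.609. The inverse slope was 0.659. Without the p53 targets r was 0.385. The share of genes near Trp53 was 14.3% within 10 Mb. An estimated correlation left 5, 5, 0, 4 and 3 lists of 15, 17, 16, 9 and 14. The directional test of fry called 0 lists without irradiation, 5 after it and 6 for the interaction. For irradiation in WT it dropped 4 of the 15 lists and newly called 1. In the mutant it dropped 6 of the 17 and newly called 1. The newly called list was the BCL2 family and caspases in both genotypes.

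The 17 list values that reversed were these adjusted p. With fry they were 0.932 for stroma and endothelium (irradiation in WT) and 0.993 for mature single positive thymocytes (in the mutant). The other 15 came with genes above the median level, hence fewer genes. They were DNA damage genes (0.869) and NF-kB targets (0.975) for irradiation in WT, DNA damage genes (0.878), mature single positive thymocytes (0.885) and natural killer cells (0.797) in the mutant, and p53 targets (0.44) and double positive thymocytes (0.967) for the genotypes without irradiation. After irradiation they were G2/M (0.947), G1/S (0.575), endoplasmic reticulum stress and oxidative phosphorylation (both 0.861), B cells (0.647), thymic epithelium (0.916) and stroma and endothelium (0.575), and for the interaction DNA damage genes (0.891).

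Leaving out 1 array gave 447 to 909 genes for irradiation in WT, 146 to 329 in the mutant, 3 to 9 without irradiation, 40 to 259 after irradiation and 14 to 56 for the interaction. The extremes came from irradiated WT mouse 1 (447, 40 and 14), irradiated WT mouse 2 (259), non-irradiated WT mouse 1 (909 and 3), non-irradiated mutant mice 2 (9), 3 (56) and 4 (146), and irradiated mutant mouse 1 (329). The score difference without irradiation lay between −0.03 and 0.001 (the reversed value, without non-irradiated WT mouse 1), the WT median between 0.512 and 0.572, the mutant median between 0.254 and 0.332, and their difference between −0.295 and −0.213.

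Replicate numbers as a replicate block gave 148 genes for the genotypes after irradiation. Of 18 pairs with the same number, 6 had a correlation of residuals above 0.1, within a range of −0.159 to 0.45. Pairs with different numbers were not compared, so whether the numbers pair the mice was not settled.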

Other observations

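Further named genes changed after irradiation in the planned fits. Dctd, which deaminates deoxycytidine monophosphate, fell by 1.10 ± 0.16 in WT and by 0.98 ± 0.13 in the mutant (log2 fold change ± SE). Shmt1, a serine hydroxymethyltransferase, and Lap3, an aminopeptidase, fell by 0.92 ± 0.12 and 0.90 ± 0.13 in the mutant. The orphan receptor gene Gpr25 fell by 1.51 ± 0.22 in WT and 1.02 ± 0.18 in the mutant, and Tmem97, a sterol-related membrane protein gene, by 1.24 ± 0.18 and 0.93 ± 0.14. Spib rose in both genotypes, by 1.35 ± 0.19 and 0.81 ± 0.15, although it had been listed as a B cell marker and Bank1 in that list fell by 0.80 ± 0.15 in WT.

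Rpf2, a factor of ribosome assembly outside the ribosome biogenesis list, fell by 1.09 ± 0.12 in WT. Slc35f2, a transporter gene, fell by 1.12 ± 0.19 in the same mice, and Tubb3, a tubulin gene, by 0.89 ± 0.13 in the mutant. After irradiation Igsf23 (1.33 ± 0.29) and the zinc finger gene Zfp932 (1.07 ± 0.22) were higher in the mutant than in WT, and Lrp12 was higher by 0.89 ± 0.13, next to 0.72 ± 0.11 without irradiation.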
